A study of Bos taurus with 6 samples.

How the data were processed

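Two-colour expression arrays of bovine granulosa cells were analysed, 3 on each of 2 slides, comparing cells of cows given cetrotide with cells of control cows 68 hours after the last FSH injection. Per the labels' protocols, cells were washed and frozen, total RNA was extracted with a kit for very small samples and amplified over 2 rounds with T7 RNA polymerase, and the product was labelled chemically with Cy3 or Cy5. Per the labels, cetrotide RNA carried Cy5 on slide 1 and Cy3 on slide 2. Dye orientation and slide therefore go together, and both cancel in an average over the slides. Amplification from small amounts can raise the spread between samples, and chemical labelling of guanines can give gene-specific dye bias.

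The deposited scanner tables hold spot intensities, mean and median pixel values of the spot and of its local background at 532 nm (Cy3) and 635 nm (Cy5), per the file headers not background corrected. The scanner, its software and its settings are not given in the sources used here. Each table had 45220 spots, of which 43794 were gene probes with 1 spot each and 153 were negative control spots. The 14 column summaries at the end of each table were left out. The authors also deposited a table of processed log ratios, taken here as log2. Set against the scanner values its slopes on log2 median-pixel ratios ran from 0.807 to 1.00 per array, with correlations across probes from 0.984 to 0.996. All of its columns ran cetrotide over control: on slide 2 the correlation with log2 Cy5 over Cy3 was -0.878 to -0.937. Its column medians were -0.00191, -0.000108, 0.000134, 0.00229, 0.00214 and 0.00748. The steps by which the authors centred and normalized it remain unknown, and it served as an alternative.

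Mean spot intensities were background corrected with normexp (offset 50) on the median local background, and log2 ratios were normalized within arrays by loess with control spots at weight 0, using limma 3.58.1 in R 4.3.3. No normalization between arrays was applied. Ratios were turned to cetrotide over control. A probe counted as above background where its intensity exceeded the 95th percentile of the negative control spots of that array and channel, and was kept if this held for either RNA on at least 4 of 6 arrays, which left 31769 probes. At most 12 probes per array were near saturation. A gene was represented by its kept probe with the highest mean log2 intensity. An unnamed probe stood for itself. Symbols came from the platform annotation, in which 21790 probes had 1 symbol, 0 had several and 22004 had none. Symbols of 1524 probes were updated through synonyms in the RefSeq gene table of the ARS-UCD2.0 assembly, and 21549 probes then had a symbol in that table. The comparison held 12389 named genes and 15040 unnamed probes. Of 2915 named genes with several kept probes, 1214 had probes of both signs.

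Median probe intensity per array and RNA lay between 107 and 313, and the median negative control between 78.7 and 247. Signal over background was thus low for many probes, and ratios of dim probes are pulled towards 0 by the offset. For genes not well above background for 1 RNA on any array, a lower bound is given: the mean of the brighter RNA over the replicates against, per array, the higher of the probe's own value and the lowest value among probes above background, as log2 channel values after loess and Aquantile. The bound is on the mean fold over the replicates, and single replicates can fall below it.

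The design text names 3 cows per condition but the labels do not say which cows share an array. The area numbers were checked: the deviations of arrays from their slide's mean correlated at 0.900, 0.934 and 0.954 for arrays with the same area number and between -0.706 and -0.00759 for the others, across genes. The deviations of a slide sum to 0 for each gene, which by itself pushes the others below 0. The ratios themselves correlated at 0.618, 0.434 and 0.759 for same-area arrays and between -0.0294 and 0.304 for the others. Same-area arrays were averaged into 3 dye-swap replicates. Whether each average holds a separate cow of each condition is not given in the sources used here, so p-values measure the spread between these samples. Limma (lmFit with an intercept, eBayes) tested the 3 averages against 0, with Benjamini-Hochberg adjustment over 27429 tests and a threshold of 0.05. Gene lists with at least 5 measured genes were tested with camera (preset correlation 0.01), beside camera with an estimated correlation and fry. A percentile of a list's median in a replicate was taken among 10000 random lists of the same size matched on mean intensity.

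The design, the lists and the rule for named genes were fixed before the data were examined. The rule took up to 12 genes per direction past the threshold. As none passed, it took genes with a symbol, the same sign on all 6 arrays and at least 1.5-fold, by ascending p, together with up to 4 members per list by p and 9 genes of the gonadotropin response. For lists that did not pass, the text names 2 members, a limit set after the results were seen. Alternatives covered background correction, normalization within and between arrays, the filter, the choice of probe, the authors' values, the treatment of the dye swaps, each slide, each left-out replicate, the variance model, the threshold and the gene set test. Median pixel values were added after the data were seen.

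The averaging, the fit and the list test were tested on simulated log ratios for 27429 genes with the spread of the cetrotide comparison. Background correction, loess, the filter and the choice of probe were not part of it. Genes were drawn independently of each other, and the changed genes were picked at random, whatever their spread. Of 100 genes changed by log2 1, 20 passed the adjusted threshold, and of 100 changed by log2 2, 70 passed. Of the unchanged genes 5.87% had an unadjusted p under 0.05, and 4 passed the adjusted threshold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.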

Results

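Transcript levels were measured in granulosa cells, the hormone-producing cells that line the inside of the ovarian follicle, from multiparous Holstein cows. The cells were aspirated from pre-ovulatory follicles of cows stimulated with gonadotropins and then coasted, that is, left without further follicle stimulating hormone (FSH), for 68 hours before ovum pick-up. Cells of 3 cows given cetrotide were compared with cells of 3 control cows. Cetrotide is a trade name of cetrorelix, an antagonist of gonadotropin releasing hormone that lowers the release of luteinizing hormone (LH) from the pituitary. The comparison asked which transcripts of coasted follicles differed when this hormone was blocked. The 6 two-colour arrays each carried cetrotide RNA and control RNA. On the 3 arrays of slide 1 the cetrotide RNA was labelled with Cy5, and on the 3 arrays of slide 2 with Cy3. Arrays with the same area number on both slides were averaged as 1 dye-swap replicate, so that n = 3 throughout. Between 53.5% and 82.5% of the probes were above the background limit per array and RNA, and 27429 genes and unnamed probes were compared. The number of arrays limits the precision.

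No single gene passed the adjusted threshold, and among genes with a symbol, the same sign on all 6 arrays and at least 1.5-fold, those with the smallest p were MRAS, TNFRSF12A and FOSL1 on the higher side and RWDD3, RSPH3 and EXOSC9 on the lower side. FOSL1, an AP-1 transcription factor subunit, had a log2 ratio of cetrotide over control of 3.01 ± 0.33 (SD, n = 3). TNFRSF12A, the receptor of the cytokine TWEAK, had 1.82 ± 0.13, and MRAS, a Ras family GTPase, 1.45 ± 0.06. RWDD3, a protein that promotes sumoylation, had a log2 ratio of -1.54 ± 0.11, the radial spoke protein RSPH3 -1.01 ± 0.04 and EXOSC9 of the RNA exosome -0.96 ± 0.03. Each of these genes had an adjusted p of 0.178 with limma, the lowest of any gene. In a fit of all 6 arrays with the area number as a random block, these 6 genes had adjusted p from 0.0156 to 0.0261, and 21 of the 24 genes named by p passed. The 24 genes were chosen by p from the same arrays, so their passing is no separate support. The block fit takes 6 arrays and a consensus correlation of 0.852 for all genes, where the main fit takes 3 averages. The SDs are over averages of both slides and leave out differences between them: MRAS had 0.70 on slide 1 and 2.20 on slide 2, CPLX1 0.26 and 1.65, NSG2 0.56 and 1.76, and MGRN1 0.59 and 1.57.

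Of the 12 named genes with the smallest p among those higher with cetrotide, the other 9 were MCC, RABEP2, NSG2, NEURL4, the ubiquitin ligase MGRN1 and the ubiquitin-conjugating enzyme UBE2L3, the growth factor MDK (midkine), the vesicle fusion regulator CPLX1 and the spermidine synthase SRM. Their mean log2 ratios ran from 0.96 for CPLX1 to 1.41 for RABEP2. MDK was above the background limit for control RNA on 3 of the 6 arrays. The 12 genes on the lower side also held the nuclear export receptor XPO1 (-1.15 ± 0.12), the spliceosomal protein LSM5 (-1.13 ± 0.13), the histone variant H2AZ2, the histone methyltransferase SUV39H2 (-0.82 ± 0.04) and the tRNA modifying enzyme TYW3 (-1.16 ± 0.13). The others were PRXL2C, CWF19L1, KIZ and CCDC59. With H2AZ2 they had mean log2 ratios from -1.08 for PRXL2C to -0.75 for CCDC59. Of the genes with several kept probes, MRAS had another probe at 0.49, PRXL2C at -0.55, LSM5 at -0.85 and H2AZ2 at -0.95, while XPO1 and SUV39H2 had other probes near 0 (0.02 and 0.05).

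**Figure D1:**
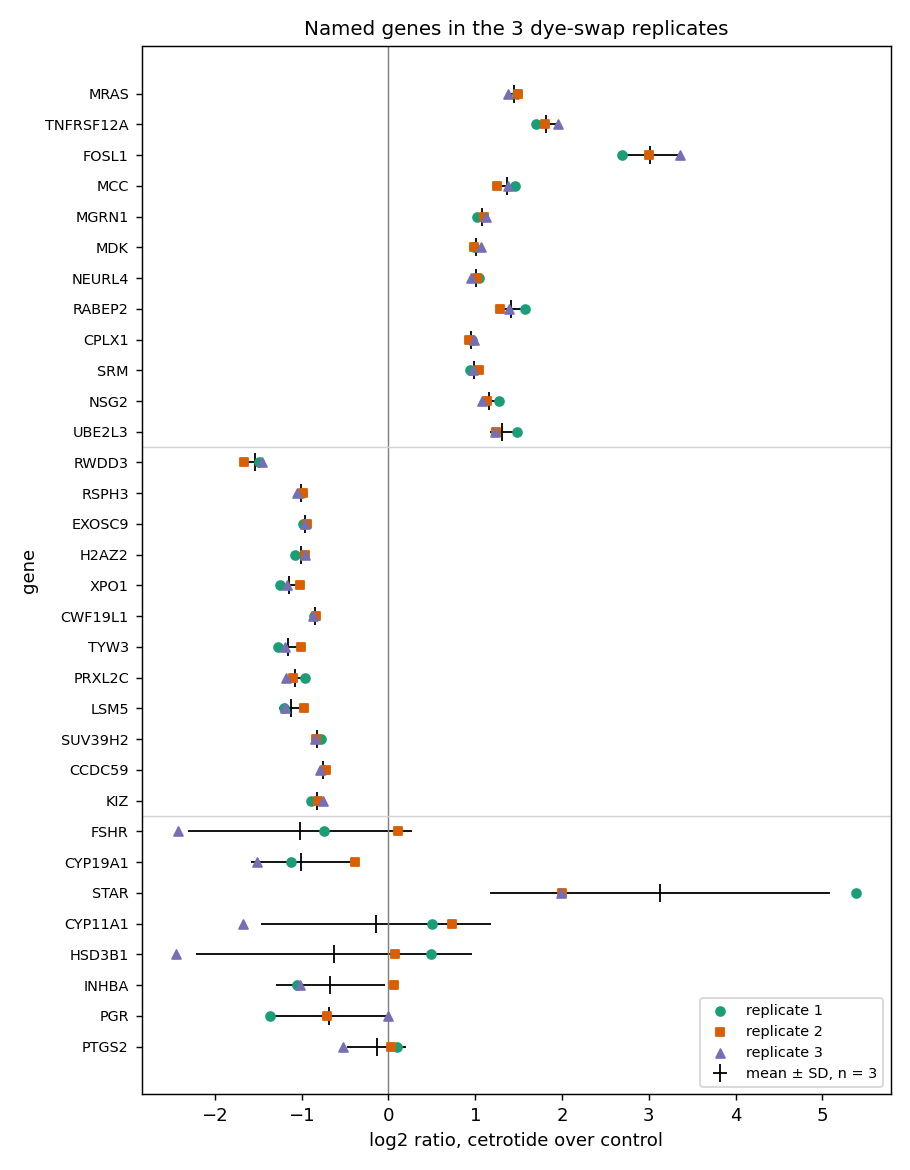
Log2 ratio of cetrotide over control (horizontal axis) for the genes named by p and for the gonadotropin response genes (vertical axis), with 1 coloured symbol per dye-swap replicate and the mean and SD of the 3 replicates in black. FOSL1 lies between 2.69 and 3.35 in the replicates, whereas FSHR spreads from -2.43 to 0.11 and STAR from 1.99 to 5.39.

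Across all 27429 tests, limma called 0 genes higher and 0 lower with cetrotide at an adjusted p under 0.05, against 3964 genes at an unadjusted p under 0.05, where chance alone would give 1371 on average. Of those, 1098 were at least 1.5-fold higher and 796 at least 1.5-fold lower. Without replicate 1, 1933 genes had an unadjusted p under 0.05 with limma, and 473 of them were at least 1.5-fold lower. Genes that move together make counts by chance spread widely around their average, so the excess over 1371 does not by itself show an effect. On slide 1 alone 0 and 0 genes passed the adjusted threshold, and on slide 2 alone 662 higher and 225 lower, where dye effects do not cancel. With all 6 arrays, a dye term and the area number as a random block (consensus correlation 0.852), 411 genes passed as higher and 264 as lower. Across genes, the mean log2 ratios of the 2 slides correlated with r = 0.491, and those of the replicates with r = 0.499 (replicates 1 and 2), 0.417 (1 and 3) and 0.256 (2 and 3); genes are not independent replicates.

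**Figure D2:**
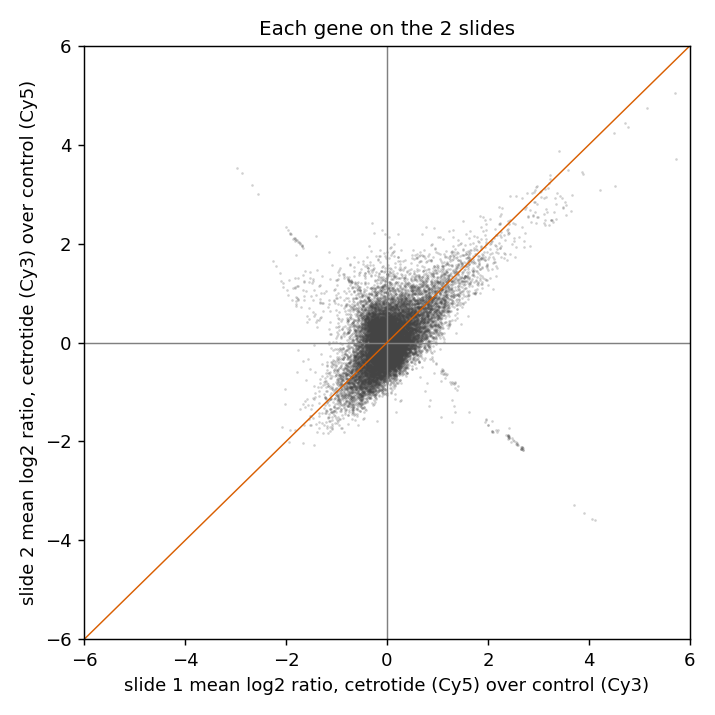
Mean log2 ratio of cetrotide over control of each gene on slide 1 (horizontal axis, cetrotide RNA in Cy5) against slide 2 (vertical axis, cetrotide RNA in Cy3), 1 point per gene or unnamed probe, with the line of equality in orange. Points off that line differ between the dye orientations, and the correlation across genes is 0.491.

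Of 23 gene lists fixed beforehand, 12 shifted by the camera gene set test with a preset inter-gene correlation of 0.01: 9 upward and 3 downward. None of the 12 passed with an estimated correlation, where the lowest adjusted p of any list was 0.660. Over the 12 lists that correlation ran from -0.0468 (atresia and apoptosis) to 0.726 (cell cycle), with 0.634 for endothelial markers. The preset test takes the genes of a list as nearly independent, so its p-values rest on that assumption. The test with an estimated correlation rests on the 2 residual degrees of freedom of 3 averages. It has little power, and a list that did not pass it may still have shifted. Atresia and apoptosis, despite a correlation of -0.0468, had a camera p of 0.00362 with the preset and 0.0860 with the estimate. The directional fry test, which asks whether the genes of a list move on balance in 1 direction and makes no comparison with other genes, passed 1 list, atresia and apoptosis. No member of any list passed adjusted over all genes, and 17 passed adjusted over the list alone.

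The cell cycle list fell with cetrotide by camera, without any member passing alone. The median log2 ratio of the 40 measured genes of S phase and mitosis was -0.52, 34 of them were below 0, and the list had a camera adjusted p of 0.000108 (adjusted p = 0.660 with an estimated correlation). At an unadjusted p under 0.05, 7 members were lower and 1 higher, and 0 passed adjusted over the list alone. CDK1, the kinase that drives entry into mitosis, had a log2 ratio of -0.84 ± 0.45, CCNE2 (cyclin E2) -0.54 ± 0.29 and the replication helicase subunit MCM4 -0.61 ± 0.23. MCM2, of the same helicase, had 0.87 ± 0.36, with another of its 3 probes at -0.14. The list median was -0.25 in replicate 1, -0.04 in replicate 2 and -1.35 in replicate 3, and it was -0.11 without replicate 3 and -0.80 without replicate 2. In the same replicates the median of the 21 measured genes that mark granulosa cells was -0.15, 0.11 and -1.13.

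Genes of the mitochondrial respiratory chain and of sterol synthesis also fell as lists. The 51 subunits of oxidative phosphorylation had a median log2 ratio of -0.22 (camera adjusted p = 0.00422, and adjusted p = 0.660 with an estimated correlation). Of these, 13 were lower and 4 higher at an unadjusted p under 0.05, and 7 passed adjusted over the list alone. Without replicate 1 the median was -0.15. NDUFV2 of complex I had -1.01 ± 0.24, NDUFA5 -0.67 ± 0.05, NDUFB3 -0.53 ± 0.10 and COX6C of complex IV -0.59 ± 0.05. The 20 measured genes of cholesterol synthesis and uptake had a median of -0.36 (camera adjusted p = 0.00422, and adjusted p = 0.660 with an estimated correlation), with 5 members lower and 0 higher at an unadjusted p under 0.05, and 0 passing adjusted over the list alone. Its median was -0.53, -0.31 and -0.11 in replicates 1, 2 and 3, and -0.14 without replicate 1. Squalene synthase FDFT1 had a log2 ratio of -0.76 ± 0.27, with its other probe at 0.01. ACAT2 had -0.72 ± 0.26, the farnesyl diphosphate synthase FDPS -0.61 ± 0.20 with another of its 4 probes at -0.03, and GGPS1 -0.34 ± 0.10. On slide 2 alone neither list passed, with camera adjusted p of 0.132 and 0.0532.

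The list that joins cAMP response genes and immediate early response genes rose by camera. The median log2 ratio of the 23 measured members was 0.51, 21 of them were above 0, and the list had a camera adjusted p of 0.000190 (adjusted p = 0.660 with an estimated correlation). At an unadjusted p under 0.05, 6 members were higher and 0 lower, and 1 passed adjusted over the list alone. The median was 0.55, 0.19 and 0.75 in replicates 1, 2 and 3, 0.28 without replicate 3 and 0.78 without replicate 1. The AP-1 subunit JUNB had a log2 ratio of 1.54 ± 0.30, MYC 1.03 ± 0.45, the nuclear receptor NR4A1 0.99 ± 0.52 and the antiproliferative gene BTG2 0.80 ± 0.30. The list of 32 measured genes that the ovulatory LH surge induces had a median of 0.14 and passed (camera adjusted p = 0.0249, and adjusted p = 0.660 with an estimated correlation), with 7 members higher and 1 lower at an unadjusted p under 0.05, and 2 passing adjusted over the list alone. Its median was 0.30, 0.00 and 0.37 in replicates 1, 2 and 3, where that of endothelial markers was 0.99, -0.05 and 0.66 and that of leukocyte markers 0.49, -0.05 and 0.90. Besides FOSL1, the tissue plasminogen activator PLAT had 2.68 ± 0.57 and the neuropeptide precursor NTS 3.85 ± 1.42, above the background limit for control RNA on 2 of the 6 arrays. The cathepsin probe named CTSL1 had -0.96 ± 0.34. Of the LH list, 21 members were above 0 and 11 below. Of those named beforehand, the progesterone receptor PGR had -0.69 ± 0.68 and the prostaglandin synthase PTGS2 -0.13 ± 0.34, adjusted p of 0.449 and 0.774 with limma. PTGS2 was dim, with a mean log2 intensity of 7.02, and above the background limit on 5 of 6 arrays for each RNA. The LH list had a median of 0.35 without replicate 2, and did not pass without replicate 3 (camera adjusted p = 0.245) or on slide 2 alone (0.217).

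Genes of the extracellular matrix and of theca cells, which lie outside the granulosa layer, rose as lists. The 31 measured matrix genes had a median log2 ratio of 0.50 (camera adjusted p = 0.000225, and adjusted p = 0.660 with an estimated correlation), with 6 higher and 0 lower at an unadjusted p under 0.05, and 0 passing adjusted over the list alone. Its median was 1.28, 0.17 and 0.32 in replicates 1, 2 and 3, and 0.20 without replicate 1. Fibronectin FN1 had a log2 ratio of 5.38 ± 2.58 and the perlecan gene HSPG2 1.00 ± 0.71. The fibrillar collagen gene COL1A2, on both lists, had 4.37 ± 3.09 and was above the background limit for control RNA on 3 of 6 arrays. The basement membrane collagen COL4A2 was not well above background for control RNA on any array and was on average at least 2.97-fold higher with cetrotide (adjusted p = 0.268 with limma). The 19 theca markers had a median of 0.30 (camera adjusted p = 0.0219, and adjusted p = 0.660 with an estimated correlation), with 2 higher and 1 lower at an unadjusted p under 0.05, and 0 passing adjusted over the list alone. COL3A1 had 4.58 ± 4.00, and its values of 8.37, 0.40 and 4.98 in replicates 1, 2 and 3 show the spread. The hedgehog receptor PTCH1 had -1.01 ± 0.44, with another of its 3 probes at 0.10. Of the 19 theca markers 15 were above 0 and 4 below, and 5 are also on the matrix list, so the lists are not separate results. Outside the naming rule, the steroid enzyme CYP17A1 had 0.03 ± 0.12, above the background limit for control RNA on 3 of 6 arrays. PDGFRA had mean log2 channel values after loess and Aquantile of 10.82 for cetrotide RNA and 10.84 for control RNA. The theca median was 0.89, 0.04 and 0.13 in the 3 replicates and 0.58 without replicate 3, and the list did not pass without replicate 1 (median 0.08, camera adjusted p = 0.141), on slide 1 alone (0.160) or on slide 2 alone (0.0532).

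Markers of endothelium and of leukocytes rose as lists, in 2 of the 3 replicates. The 15 measured endothelial markers had a median log2 ratio of 0.60 (camera adjusted p = 0.00422, and adjusted p = 0.660 with an estimated correlation), and medians of 0.99, -0.05 and 0.66 in replicates 1, 2 and 3. Only 1 member was higher at an unadjusted p under 0.05, the coreceptor ENG (0.24 ± 0.02, above the background limit for control RNA on 3 arrays, as was EMCN), and 0 passed adjusted over the list alone. The tight junction gene CLDN5 had 0.71 ± 0.53, EMCN 1.46 ± 1.14 and the VEGF receptor KDR 1.32 ± 1.17. The 22 measured leukocyte markers had a median of 0.48 (camera adjusted p = 0.00456, and adjusted p = 0.660 with an estimated correlation), and medians of 0.49, -0.05 and 0.90. CD74, the invariant chain of MHC class II, was the member higher at an unadjusted p under 0.05 (1.08 ± 0.49), and 0 passed adjusted over the list alone. BOLA-DRA of MHC class II had 1.57 ± 1.22, the chemokine receptor CXCR4 1.15 ± 1.02 and GZMB (granzyme B) 0.85 ± 0.65. Of the 22 leukocyte markers 19 were above 0 and 3 below. Outside the naming rule, PTPRC (CD45) had mean log2 channel values after loess and Aquantile of 8.27 for cetrotide RNA and 8.24 for control RNA. LAPTM5 had 9.77 and 8.32. Without replicates 1 and 2 in turn, the endothelial median was 0.36 and 0.96. Without replicates 1, 2 and 3 in turn, the leukocyte median was 0.23, 1.10 and 0.28. The endothelial list did not pass without replicate 3 (camera adjusted p = 0.0564), nor the leukocyte list on slide 2 alone (0.0956).

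Interferon-stimulated genes and genes of apoptosis and follicular atresia rose as lists. The 30 measured interferon-stimulated genes had a median log2 ratio of 0.23 (camera adjusted p = 0.00490, and adjusted p = 0.660 with an estimated correlation), with 5 higher and 0 lower at an unadjusted p under 0.05, and 1 passing adjusted over the list alone. Their median was 0.09, 0.10 and 0.47 in replicates 1, 2 and 3, where that of leukocyte markers was 0.49, -0.05 and 0.90 and that of the epithelial markers listed afterwards 0.02, 0.50 and 1.85. IFITM3 had 0.93 ± 0.12 with its other probe at 0.30, the transcription factors IRF1 0.83 ± 0.38 and IRF7 1.86 ± 0.89, and IFI27 0.69 ± 0.36, with its other probe at -0.08. These members had the smallest p of the list, in which 23 members were above 0 and 7 below. Outside the naming rule, ISG15 had mean log2 channel values after loess and Aquantile of 8.81 for cetrotide RNA and 9.24 for control RNA. HERC5 had 10.91 and 11.14. The 21 measured apoptosis and atresia genes had a median of 0.24 (camera adjusted p = 0.00926, adjusted p = 0.660 with an estimated correlation, and fry adjusted p = 0.0136). Of them 5 were higher and 0 lower at an unadjusted p under 0.05, and 3 passed adjusted over the list alone. The stress-induced genes GADD45G and GADD45B had 1.76 ± 0.37 and 1.93 ± 0.71, and the secreted chaperone clusterin CLU 1.58 ± 0.48. IGFBP5, an IGF binding protein, was not well above background for control RNA on any array, and was above it for cetrotide RNA on 4. On average it was at least 1.40-fold higher (adjusted p = 0.336 with limma), with log2 ratios of 0.96, 0.63 and 0.15 in replicates 1, 2 and 3. The interferon list did not pass without replicate 3 (median 0.11, camera adjusted p = 0.117), and the apoptosis list, with a median of 0.12 without replicate 1, did not pass without replicate 2 (median 0.12, camera adjusted p = 0.0623) or on slide 2 alone (0.0572).

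Among genes of steroid synthesis and luteinization, the cholesterol transporter STAR was higher in each replicate and the aromatase CYP19A1, which makes oestradiol, lower in each, without passing the adjusted threshold. STAR had a log2 ratio of 3.13 ± 1.96 (5.39, 2.00 and 1.99) and CYP19A1 -1.01 ± 0.57, adjusted p of 0.291 and 0.271 with limma. STAR is also on the theca list, whose median was 0.89 in replicate 1 where STAR was highest, and another of the 3 CYP19A1 probes gave -0.10. The FSH receptor FSHR had -1.02 ± 1.29, the inhibin and activin subunit INHBA -0.67 ± 0.63, HSD3B1 -0.63 ± 1.59 and CYP11A1 -0.15 ± 1.33, with adjusted p from 0.435 to 0.941. Without replicate 3 the values of CYP11A1, HSD3B1 and PTGS2 turned to 0.61, 0.28 and 0.06. The LH receptor LHCGR was not compared, since its 2 probes were above the background limit on at most 3 of the 6 arrays. The steroidogenesis list of 21 measured genes did not shift (median 0.00, camera adjusted p = 0.927), with 2 members higher and 2 lower at an unadjusted p under 0.05, and 2 passing adjusted over the list alone. HSD3B7 had 0.81 ± 0.06 and the nuclear receptor NR5A2 -1.20 ± 0.39, although another of the 3 NR5A2 probes gave 1.02. The luteinization list of 20 genes rose (median 0.24, camera adjusted p = 0.0219, and adjusted p = 0.660 with an estimated correlation), with 7 higher and 0 lower at an unadjusted p under 0.05, and 0 passing adjusted over the list alone. Its members with the smallest p were the keratins KRT8 (3.06 ± 1.25) and KRT18 (1.84 ± 1.02), the collagen crosslinking enzyme LOXL4 (2.08 ± 1.18) and oxytocin OXT (0.29 ± 0.07). KRT8 and KRT18 are also keratins of simple epithelia. KRT8 was at 4.18, 1.71 and 3.30 in replicates 1, 2 and 3, and a list of epithelial markers written after the data were seen had medians of 0.02, 0.50 and 1.85 there. OXT was positive on 3 arrays and negative on the 3 others, by slide. The luteinization list did not pass without replicate 2 (camera adjusted p = 0.0507), on slide 1 alone (0.386) or on slide 2 alone (0.0532).

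The other lists did not pass the camera threshold. Granulosa identity genes had a median log2 ratio of -0.27 (camera adjusted p = 0.0700, 2 of 21 lower and 0 higher at an unadjusted p under 0.05), and the smallest p belonged to NR5A2 and CYP19A1. Hypoxia and angiogenesis genes had -0.34 (0.0688), with 2 of 31 higher and 2 lower. The stress-induced inhibitor of mTOR signalling DDIT4 had -1.17 ± 0.40 and endothelin EDN1 0.24 ± 0.08, above the background limit for control RNA on 1 array. Without replicate 2 both of these lists passed, with medians of -0.70 and -0.59 and camera adjusted p of 0.00120 and 0.00142. Without replicate 1 the medians were -0.48 and -0.21, and without replicate 3 that of hypoxia genes was -0.13. Inhibin, activin and BMP signalling genes had 0.33 (0.0700), or 0.09 without replicate 1, with 5 of 27 higher and 1 lower. SMAD4 had 0.78 ± 0.17 with another of its 3 probes at 0.05, while BMP4, not well above background for control RNA on any array, was on average at least 1.41-fold higher (adjusted p = 0.193 with limma). The IGF system had a median of -0.01 with a mean of 0.63 and an upward test direction (camera adjusted p = 0.125), with 4 of 15 higher and 0 lower. With a random block for the area number, 3 of these lists passed: granulosa identity (camera adjusted p = 0.0281), hypoxia (0.0259) and BMP signalling (0.0167). Under median centring in place of loess, granulosa identity (0.0279) and hypoxia (0.0156) passed. The leading member of the IGF system was the growth factor IGF2 at 4.72 ± 2.01, whose other 2 probes reached down to 0.06, followed by IGF2R at 0.81 ± 0.46. Without replicate 3 the IGF and BMP lists passed, both with a camera adjusted p of 0.0452.

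Lists of protein folding, translation and remaining cell types had medians near 0 over the replicates. Unfolded protein response genes had a median log2 ratio of 0.03 (camera adjusted p = 0.681), with a mean of -0.00 and a median of -0.07 under median centring. Of the 25 measured, 2 were higher and 1 lower at an unadjusted p under 0.05, and 1 passed adjusted over the list alone. PPP1R15A had 1.26 ± 0.24, above the background limit for control RNA on 3 arrays, and PDIA3 0.47 ± 0.20. Heat shock genes had 0.01 (0.979), or -0.10 under median centring, with 2 of 20 higher and 2 lower, among them BAG3 (0.82 ± 0.21) and AHSA1 (-0.63 ± 0.42). Ribosomal proteins had a median of 0.03 against a downward test direction (0.927), with 0 of 60 higher and 4 lower. That median was -0.14 under median centring, where the list passed (camera adjusted p = 0.00391). In replicates 1, 2 and 3 it was 0.30, 0.10 and -0.34. The list passed downward without replicate 1 (0.0344), and upward without replicate 3 (0.000211) and on slide 1 alone (0.0326). RPS26 had -0.63 ± 0.13, and RPS13 -0.44 ± 0.05 with opposite signs on the slides. Hormone receptor genes had a median of -0.04 and a mean of 0.05 (0.979), with 2 of 26 higher and 2 lower, led by BMPR1A (0.49 ± 0.17) and PGRMC2 (-0.36 ± 0.14), each with another probe of the opposite sign (-0.11 and 0.29). Red blood cell markers had 0.09 (0.533), with 0 of 6 members at an unadjusted p under 0.05, SLC4A1 at 0.30 ± 0.24 and EPB42 at 0.14 ± 0.05. Oocyte markers had a median of -0.03 and a mean of 0.00 (0.927), with 0 of 14 at an unadjusted p under 0.05, H1-8 at 0.15 ± 0.02 and DDX4 at -0.17 ± 0.21.

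**Figure D3:**
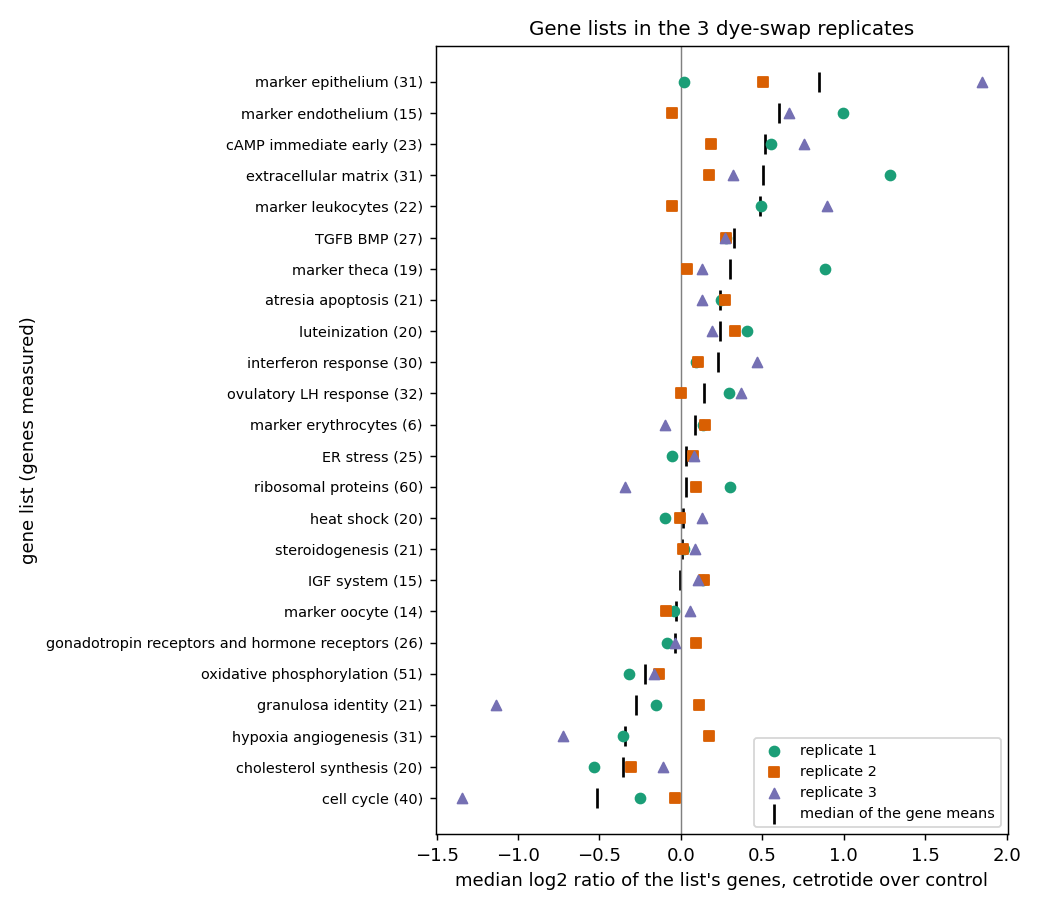
Median log2 ratio of cetrotide over control (horizontal axis) of the genes of each list (vertical axis, genes measured in parentheses), with 1 coloured symbol per dye-swap replicate and the median of the gene means as a black bar; the epithelial list was added after the data were seen. The cell cycle median lies at -1.35 in replicate 3 and at -0.04 in replicate 2, and the endothelial median at 0.99 in replicate 1 and -0.05 in replicate 2.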

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

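The tests of the marker and cell cycle explanations, and the test of the slide difference, were chosen after the result was seen; the counts over sign patterns of the replicates were planned. Ratios differed between the dye orientations for most genes. A limma test of slide 1 minus slide 2 within each area found that the log2 ratio differed between the dye orientations for 16187 of 27429 genes. Of 109 genes named in the text it differed for 71. A few genes given outside the naming rule are not among these 109. All arrays of slide 1 opposed all arrays of slide 2 for 16.8% of genes, while all 6 arrays had one sign for 15.3%. Among the 109 genes this split held for OXT, with a slide difference of -1.67 in log2 ratio, and for RPS13, with 1.20. Both differences also passed the test. Slide and dye cannot be told apart in this design.

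Signal also appeared in control spots outside the comparison. The 320 spots for the viral transcript E1A had median intensities at least 21.5 times the background limit in every array and channel, and the 36 spots named DCP at least 18.8 times. The labels do not say whether transcripts were added to the samples.

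Chance could not be excluded from the number of replicates. The 3 replicates allow 4 sign patterns, too few for a share under 0.05. For genes at an unadjusted p under 0.05 and at least 1.5-fold, the real pattern gave 1894 and the highest of the others 566, so 1 of 4 patterns gave as many. For gene lists it gave 12 against 10, again 1 of 4. For genes past the adjusted threshold all 4 patterns gave 0.

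Markers of endothelium, leukocytes and epithelium were higher with cetrotide in some replicates and not in others. An epithelial list of 40 genes, 31 of them measured and 0 shared with another list, was written after high epithelial genes had been seen, and had medians of 0.02, 0.50 and 1.85 in replicates 1, 2 and 3. In replicate 3, 20 of its members were over 2-fold higher and 0 over 2-fold lower, and the members with the highest mean intensity over both RNAs, a rank that a rise itself lifts, were DSG2, SPINT2, EPCAM and TSPAN1, with log2 ratios of 1.09, 0.65, 5.02 and 3.33 there. CDH3 had -0.42. RNA of other cell types in the cetrotide samples stays open: the epithelial median reached 1.85, but the list was chosen after such genes were seen, so that value is no support for it, and the labels name aspiration and no sort. A lower share of granulosa cells, with the other cells in fixed proportions, stays open too. Among theca, endothelial and leukocyte markers above background (14, 14 and 19 members), the largest difference of medians between lists and between replicates 1 and 3 was 1.57 (theca and leukocytes, 95% bootstrap interval over genes -0.12 to 3.51). The same value for 14 endothelial and 18 epithelial members above background was 2.13 (0.53 to 3.68), which rests on the list chosen afterwards. A response of the granulosa cells stays open. The lowest percentile of a list median among random lists was 22.27, which neither opposes nor shows a rise in every replicate. That percentile cannot decide the question, since RNA of other cells could raise these lists as well and a granulosa response need not.

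The cell cycle list was lower with cetrotide, mostly in replicate 3. A bias between dyes or slides is argued against by the shared sign, since the median was -0.49 on slide 1 and -0.60 on slide 2. The list passed on each (camera adjusted p of 4.38e-05 and 0.0252). Those passes add little, since they use the preset correlation where the estimate over the replicates was 0.726. The slides are dye swaps of the same replicates and not separate tests. Dilution of granulosa RNA by RNA of other cells could lower the list and stays open: the cell cycle median minus the granulosa median was -0.24 (95% bootstrap interval over genes -0.67 to 0.46), and the granulosa median itself had an interval of -0.96 to 0.13. These intervals take the genes of a list as independent and do not measure the spread between samples. Less proliferation with cetrotide stays open as well, since the median was at percentile 0.19 of random lists in replicate 1, 24.53 in replicate 2 and 0 in replicate 3. The list passed without replicate 3 with a median of -0.11 (camera adjusted p = 0.0407).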

How the results depend on the processing

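All alternatives here were planned, except median pixel intensities, which were added after the data were seen. With the same-area averages kept, 0 genes passed in either direction at an adjusted p under 0.05 under every processing alternative and every left-out replicate. In the main fit 0 passed at an adjusted p under 0.1 either. With array weights the lowest adjusted p with limma was 0.0772. Higher genes made up 58.0% of those at an unadjusted p under 0.05 and at least 1.5-fold, and 50.7% under median centring. Signal over background limits the view: 31769 of 43794 probes were kept, and ratios of dim probes shrink towards 0.

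Counts moved with the treatment of the paired dye swaps. With area as a random block, 411 genes passed as higher and 264 as lower, 1701 were higher at an unadjusted p, and 15 lists passed. Without a block, 1806 and 1458 passed and 1690 were higher at an unadjusted p, since 6 arrays then count as 6 samples. Pairing slide 1 areas 1, 2, 3 with other areas of slide 2 gave higher and lower counts of 2298 and 2001 (1, 3, 2), 480 and 366 (2, 1, 3), 2337 and 2042 (2, 3, 1), 1960 and 1533 (3, 1, 2) and 1492 and 944 (3, 2, 1). Unadjusted counts were 1821 and 1206 (1, 3, 2), 2044 and 1261 (2, 3, 1), 2031 and 1255 (3, 1, 2) and 1791 higher (3, 2, 1). Such pairs average different areas, so the averages share more and spread less by construction, and these larger counts are not evidence for the pairing.

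Slide 2 alone gave 662 and 225 adjusted, 2229 and 1597 unadjusted and 5 lists; array weights gave 1695 and 1314 unadjusted. Leaving out each replicate gave 473 to 1103 lower genes unadjusted. With an estimated correlation 0 lists passed, with fry 1 (5 by its mixed test of change in either direction) and with camera on ranks 13, among them hypoxia (adjusted p = 0.0467). The cause was not tested for these, nor for the reversals below.

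Among the 109 genes of the slide test, these changed sign: PGRMC2 with probes averaged (0.00127), OXT, RPS13 and H1-8 on slide 1 (-0.54, 0.17 and -0.0121), and CYP11A1 on slide 2 (0.19). With array weights CYP11A1, HSD3B1, PTGS2 and DSG2 had 0.32, 0.0975, 0.0157 and -0.30. DSG2 also had -0.00636 with median centring and -0.28 on slide 2. Over left-out replicates the ranges were -0.59 to 0.61, -1.19 to 0.28, -0.25 to 0.0603 and -0.35 to 0.48 for these 4.

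List medians near 0 changed sign too. Steroidogenesis had -0.00238 without background correction, -0.0331 with the strict filter and -0.00459 with every probe tested. The IGF system had 0.00981, 0.39 and 0.0614 there, 0.00764 with median centring, 0.0193 with scale, 0.0513 with the authors' values, 0.0303 and 0.0480 on slides 1 and 2, 0.17 with array weights and 0.0477 with median pixels. Unfolded protein genes had -0.0698 with median centring, -0.11 on slide 1 and -0.0443 with array weights. Heat shock genes had -0.10 with median centring, -0.0332 with scale, -0.0311 and -0.0709 on slides 1 and 2 and -0.00866 with array weights. Ribosomal proteins had -0.14 with median centring and -0.10 on slide 2. Oocyte markers had 0.000113 with median centring, 0.00628 without a filter and 0.0137 with the strict one. Over left-out replicates the ranges were -0.0320 to 0.0588 (steroidogenesis), -0.0586 to 0.0469 (receptors), 0.00205 to 0.14 (IGF), -0.0215 to 0.0768 (unfolded protein), -0.0255 to 0.0179 (heat shock) and -0.0842 to 0.18 (ribosomal).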

Other observations

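The genes of this paragraph were chosen after their values were seen. With cetrotide, 13 named genes were higher by 4-fold or more in each of the 3 replicates, and 0 were lower by as much. Besides FN1, IGF2, NTS, FOSL1 and PLAT they included the iron-binding lactoferrin LTF with a log2 ratio of 3.07 ± 0.49 (SD, n = 3), DMBT1 with 3.11 ± 0.79, the serum amyloid gene SAA3 with 3.16 ± 0.96 and GP2 with 3.66 ± 1.20. The transcription factor ETS2 had 3.15 ± 1.08, LOC511937 2.93 ± 1.28 and ZFAND2A, a zinc finger gene induced by heavy metals and heat, 2.88 ± 0.65, with its other probe at 0.10. The collagen gene COL12A1 was not well above background for control RNA on any array and was on average at least 6.90-fold higher. Each of the 13 was higher on 6 of 6 arrays, and their adjusted p with limma ran from 0.178 to 0.232, so that none passed. With the area number as a random block, all but IGF2, LOC511937 and LTF (adjusted p of 0.0959, 0.0507 and 0.232) passed. That fit takes the arrays from which the 13 genes were chosen, so it is no separate support.

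The replicates differed in how far their ratios spread. The SD of the log2 ratios over genes was 0.53 in replicate 1, 0.41 in replicate 2 and 0.75 in replicate 3. Replicate 3 held 663 genes over 4-fold higher and 166 over 4-fold lower, replicate 1 held 204 and 14, and replicate 2 held 108 and 2. FSHR was at -0.75, 0.11 and -2.43 in replicates 1, 2 and 3, HSD3B1 at 0.49, 0.07 and -2.45, and CYP11A1 at 0.50, 0.73 and -1.67.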
